A study of Mus musculus with 6 samples.

How the data were processed

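Gene expression was measured on Affymetrix mogene ST arrays in CAR cells sorted by flow cytometry from the bone marrow of femur and tibia, with 1 array for each of 6 samples. Per the labels, all mice were C57BL/6, 7 weeks old, and carried Dmp1-Cre and a Cxcl12-gfp allele, and biotinylated cDNA was made with a kit for picogram to nanogram amounts of total RNA. The labels name 2 groups, CAR cells with and without targeting by Dmp1-Cre, with 3 biological replicates each. The series' design text has both populations sorted from 3 mice, with the cells of 1 mouse as 1 sample.

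The deposited values were array intensities summarised per probe set with RMA in Affymetrix Expression Console 1.4, per the submitters' processing notes. They were on a linear scale, although the design fixed beforehand had assumed log2 values, so the log2 of each deposited intensity was taken before any test. The annotation and genome build used upstream are not given in the sources used here, and no genome was used, so no coordinates are reported. The table held 35556 probe sets, and the arrays' median intensities ran from 79.4 to 87.5. No detection calls were used here, and the number of arrays limits the precision.

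Probe sets were named through the platform's annotation. Of all probe sets, 21789 named exactly 1 gene, 1621 named several and 12146 were not listed there. Symbols were updated through the Entrez identifier in the RefSeq table of GRCm38.p6, which matched 21698 of the 21789. Probe sets naming several genes or none stayed out of the gene test. For 999 genes with several probe sets, the one with the highest mean over all 6 arrays was kept, which gave 19938 genes. The 33.3% of genes with the lowest means, at or below a log2 intensity of 6.00, were left out as dim, and 13292 genes were tested.

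The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with neither an intensity trend nor a robust fit), as targeted minus non-targeted, over all 6 arrays with no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Standard errors (SE) and 95% intervals are those of the moderated fit, and SDs are between the 3 arrays of a group. Figures were drawn with matplotlib 3.10.9.

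Before the data were examined, 31 gene lists (cell types, lineages, pathways and stress responses), 20 single genes, the main fit and most of the alternative settings were written down. Of the 683 list symbols, 630 had a value and 518 passed the filter on dim genes. Of the 20 single genes, 16 were tested, 1 was dim and 3 were not analysed here. Lists with at least 5 tested members were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 30 lists tested. Each list was tested again with the correlation estimated from the arrays and with fry. A count "adjusted over the list alone" applies the Benjamini-Hochberg method to the list's members only. It is not corrected for the number of lists, so some such calls can arise by chance.

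The rule for named genes took, in each direction, up to 12 genes past the threshold whose 3 arrays of one group all lay beyond the 3 of the other. Where fewer passed, it filled the 12 with the smallest unadjusted p among non-overlapping genes of at least 1.5-fold, to be given as not passing. It added the 20 single genes, up to 4 members of each list by smallest p, and Xist with Y-linked genes as a check on which arrays could share a mouse. Predicted gene models and small RNAs were left out.

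The labels do not say that a replicate number marks a mouse, so the replicate number was left out of the fit as fixed beforehand and entered only as an alternative. This was kept after the calls with and without the replicate number had been seen. Calls given below are those of the fit without it unless stated. Other alternatives were no filter or a stricter filter on dim genes, quantile, cyclic loess or median scaling of the arrays, an intensity trend, robust variances, array weights, the mean of a gene's probe sets, and leaving out each array in turn. Fits on replicates 2 and 3 alone, without both arrays at one end of the first principal component, with the Xist class as a covariate, and with Dmp1 taken out of the lists were added after seeing the data.

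The procedure was tested on simulated data for this comparison, in 20 runs with the real genes' means, their spreads as moderated by limma, and 200 changed genes among 13292. It called 61% of genes changed 2-fold, 98.3% of those changed 4-fold, 99.5% at 8-fold and 100% at 16-fold. A list shifted by 0.46 on the log2 scale was called in 20 of 20 runs, and 1 of 520 unshifted lists was called. Genes were simulated as independent, so these runs say nothing about lists whose members vary together between arrays.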

Results

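Cxcl12-abundant reticular (CAR) cells are stromal cells of the bone marrow with a high level of the chemokine gene Cxcl12, and they express genes of both the adipocyte and the osteoblast lineage. Dmp1-Cre is a Cre transgene driven by regulatory sequence of Dmp1, a matrix protein gene of late osteoblasts and osteocytes. RNA from CAR cells that Dmp1-Cre had targeted and from CAR cells that it had not was measured on 3 arrays per population, 6 in all. The median intensities of the arrays ran from 79.4 to 87.5. Log2 values of array pairs correlated across genes at 0.91 to 0.96, and no pair held identical values. The comparison addressed how the targeted subset of CAR cells differed from the rest.

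Among the annotated genes tested, Dmp1 itself separated the populations most clearly. Its log2 intensity was 10.40 ± 0.77 in targeted cells and 7.12 ± 0.34 in non-targeted cells (SD, n = 3 each), a 9.72-fold difference (log2 difference 3.28, SE 0.37, 95% interval 2.41 to 4.15, probe set 10523693). All 3 targeted arrays, at 9.89 to 11.28, lay above all 3 non-targeted arrays, at 6.91 to 7.51. Among the 16 tested genes fixed beforehand, 3 passed when adjusted over the list alone with limma. Dmp1 rose (adjusted p = 0.000463), as did Alpl, the tissue-nonspecific alkaline phosphatase of mineralising cells (2.16-fold, log2 difference 1.11, SE 0.31, adjusted p = 0.0391). Il7, a cytokine needed by developing lymphocytes, fell by 1.03 on the log2 scale (SE 0.25, 2.04-fold, adjusted p = 0.0323). The Cre that defined the groups is driven by Dmp1 sequence, so a rise of Dmp1 tells little beyond the sort. Keeping Dmp1 in the list also lowers the adjusted p of Alpl and Il7, which were not adjusted without it. In leave-one-out fits the call of Dmp1 stayed, while that of Alpl stayed only without targeted replicate 2 and that of Il7 only without targeted replicate 1. Over the 17 alternatives in which list-alone values were taken, the adjusted p of Alpl ran from 0.00645 to 0.153 and that of Il7 from 0.00645 to 0.105.

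Over all 13292 genes tested, 0 passed limma's threshold. The smallest adjusted p was 0.384, for Dmp1, and 634 genes had an unadjusted p under 0.05, 179 higher and 455 lower in targeted cells, where about 665 were expected by chance. With the replicate number as a fixed block Dmp1 alone passed (limma, adjusted p = 0.0153), and with it as a random block Dmp1 did not pass (adjusted p = 0.9999). The arrays of the groups did not overlap for 1206 genes, or 9.07%, against 10% by chance. In the simulated comparison the same test made calls with 3 arrays per group, most of them for genes changed at least 4-fold. The 200 changed genes planted there ease the adjusted threshold, and the noise followed the moderated spreads. Dmp1, at 9.72-fold, was not called in the real data, so 0 calls do not exclude large changes of single genes.

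**Figure D1:**
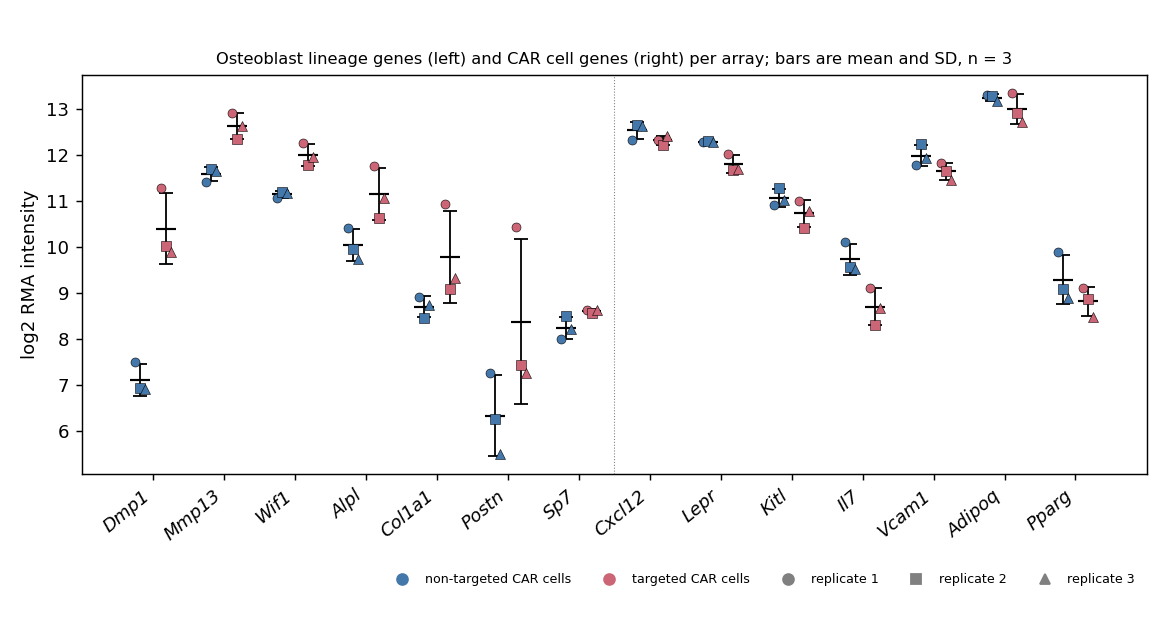
Log2 RMA intensity (vertical axis) of 14 genes on each of the 6 arrays, coloured by population and marked by replicate, with the mean and SD of 3 arrays as black bars. Dmp1 lay at 9.89 to 11.28 in targeted and 6.91 to 7.51 in non-targeted cells, while Cxcl12 was at 12.22 to 12.40 in targeted and 12.32 to 12.65 in non-targeted cells.

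Most genes of the osteoblast lineage were higher in targeted cells. Of 23 tested members, 21 were higher and 2 lower, with a median log2 difference of 0.46, and 9 had all targeted arrays above all non-targeted ones. Mmp13, a collagenase of bone remodelling, was at 12.62 ± 0.28 against 11.59 ± 0.15 (SD, n = 3), 2.05-fold higher. Wif1, a secreted Wnt inhibitor, was at 11.99 ± 0.24 against 11.15 ± 0.07, 1.80-fold higher. Both rose when adjusted over the list alone (limma, adjusted p = 0.0140 each), and 0 members passed over all genes. Alpl had a list-alone adjusted p of 0.0562 and Bmp3, a bone morphogenetic protein gene, was 1.38-fold higher without passing. Sp7, a transcription factor of osteoblasts, was at 8.61 ± 0.04 against 8.24 ± 0.24 and did not pass. The members with the highest intensities hardly differed. Sparc was at 13.12 against 13.23, Ibsp at 12.84 against 12.79 and Cdh11 at 12.49 against 12.54. The members' mean log2 intensity was 10.07 in targeted replicate 1, 9.39 and 9.44 on the other targeted arrays and 9.07 to 9.12 on the non-targeted ones. The list's camera test gave an adjusted p of 2.32e-11 at the preset correlation of 0.01. The correlation estimated from the arrays was 0.225, and with it the camera adjusted p was 0.471. The list kept its call without each array in turn, but the list-alone calls of Mmp13 and Wif1 ended without non-targeted replicate 3 (adjusted p = 0.0640 each, range 0.00438 to 0.0640 over the 17 alternatives with list-alone values).

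Most genes that mark CAR cells and marrow stroma were lower in targeted cells. Of 23 tested members, 22 were lower in targeted cells and 1 was higher, with a median log2 difference of -0.31. The members' mean log2 intensity overlapped between the groups, at 11.18, 10.84 and 10.81 on the targeted arrays and 11.10, 11.41 and 11.23 on the non-targeted ones. Cxcl12 was at 12.31 ± 0.09 in targeted and 12.53 ± 0.19 in non-targeted cells (SD, n = 3), a log2 difference of -0.22 (95% interval -0.58 to 0.15), which did not pass. Lepr, the leptin receptor, was at 11.80 ± 0.20 against 12.29 ± 0.01 (log2 difference -0.49), Grem1, a BMP antagonist, differed by -0.50 and Esm1 by -0.48. All 3 had non-overlapping arrays, and none passed. Kitl, the stem cell factor gene, differed by -0.34, Vcam1 by -0.34, Foxc1 by -0.35 and Ebf3 by -0.23, and none of the 23 members passed when adjusted over the list alone. In leave-one-out fits Kitl ran from -0.47 to -0.18, Vcam1 from -0.44 to -0.22 and Foxc1 from -0.50 to -0.17. Pdgfra differed by -0.23 and Pdgfrb by -0.11, the latter turning to 0.11 without non-targeted replicate 2 and to 0.02 without targeted replicate 2. Nes was dim, at 5.19 against 5.39. The camera test gave an adjusted p of 4.71e-06 at the preset correlation. With the estimated correlation of 0.370 the camera adjusted p was 0.484. Setting non-targeted replicate 1 with targeted replicates 2 and 3 against the rest gave nearly as small a camera p (-log10 of 5.97 against 6.50).

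The adipocyte lineage list also fell. Of 22 tested members, 19 were lower and 3 higher, with a median log2 difference of -0.22. Mgp, a matrix protein gene, differed by -0.83 (SE 0.34), Scd1, a fatty acid desaturase, by -0.75, Pnpla2, a triglyceride lipase, by -0.40 and Klf15 by -0.39. Pparg, the master regulator of fat cell formation, differed by -0.48 and Adipoq by -0.25, from a level of 13.24 ± 0.07 in non-targeted cells. No member passed alone, and in leave-one-out fits Mgp ran from -1.25 to -0.57, Scd1 from -0.99 to -0.34, Klf15 from -0.51 to -0.22 and Pparg from -0.68 to -0.18. The camera test gave an adjusted p of 0.00158, and adjusted p = 0.471 with an estimated correlation.

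Factors that support blood cell formation fell as a list by a smaller amount. Of 23 tested members, 15 were lower and 8 higher, with a median log2 difference of -0.08 and a camera adjusted p of 0.0368 (adjusted p = 0.485 with an estimated correlation). Il7 differed by -1.03 and Il15, a cytokine of natural killer cells, by -1.17 (SE 0.32), each with a list-alone adjusted p of 0.0840, and Angpt1 by -0.49 (-0.66 to -0.29 in leave-one-out fits). Csf1 was at 11.42 ± 0.13 against 11.59 ± 0.27 (SD, n = 3). The call ended without non-targeted replicate 2 (median -0.18, adjusted p = 0.227), targeted replicate 2 (median -0.11, 0.230) or targeted replicate 3 (median -0.15, 0.074), so the shift was no smaller there, and the adjusted p ran from 0.00521 to 0.552 over all alternatives.

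The osteocyte and matrix lists passed the camera threshold upward with small medians, the osteocyte list only with Dmp1 in it. In the osteocyte list 11 of 15 tested members were higher, with a median of 0.09 and a mean of 0.33. Only Dmp1 passed when adjusted over the list alone (adjusted p = 0.000434). Slc20a2, a phosphate transporter, differed by 0.76 and Fam20c by 0.39, while Phex differed by -0.22, and none of these 3 passed. In leave-one-out fits Slc20a2 ran from 0.45 to 1.00, Fam20c from 0.29 to 0.59 and Phex from -0.35 to -0.12. The camera test gave an adjusted p of 0.0308, adjusted p = 0.484 with an estimated correlation, and adjusted p = 0.159 with Dmp1 taken out. The osteocyte call also ended without non-targeted replicate 2 (median 0.065, adjusted p = 0.224) or targeted replicate 1 (median 0.061, 0.134), within a range of 0.00846 to 0.484.

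In the collagen and matrix list 19 of 32 members were higher and 13 lower (median 0.05, mean 0.22, camera adjusted p = 0.0402, adjusted p = 0.564 with an estimated correlation). Vcan, the proteoglycan versican, differed by 0.87 and Col6a3 by 0.67, whereas Fbln1 differed by -0.45 and the collagen hydroxylase gene P4ha1 by -0.43. Col1a1 was at 9.79 ± 1.00 against 8.70 ± 0.23 (SD, n = 3), with 10.93 in targeted replicate 1, and its log2 difference fell from 1.08 to 0.51 without that array. Postn, a matrix protein gene of periosteum and bone, was at 8.38 ± 1.78 against 6.34 ± 0.88 (SD, n = 3), 4.10-fold higher. It was at 10.44 in targeted replicate 1 and at 7.43 and 7.27 on the other targeted arrays, and without the first it was 2.01-fold higher. In the fibroblast and periosteal list 10 of 13 members were higher (median 0.15, camera adjusted p = 0.0402, adjusted p = 0.484 with an estimated correlation), among them Lum at 1.07, Fn1 at 1.00 and S100a4 at 0.90, with Ogn at -0.43. None of the members named passed alone, and in leave-one-out fits Fn1 fell to 0.29, Lum to 0.61, S100a4 to 0.59, Col6a3 to 0.37 and Ogn to -0.24 at the smallest. Without targeted replicate 1 both calls ended, with medians of 0.039 for collagen (adjusted p = 0.585) and 0.16 for fibroblast genes (0.444). They also ended without non-targeted replicate 2 (0.021, adjusted p = 0.130, and 0.11, adjusted p = 0.307). The collagen call ended without non-targeted replicate 3 (0.0063, adjusted p = 0.0720) and the fibroblast call without non-targeted replicate 1 (0.21, adjusted p = 0.0608), so without either replicate 1 array the fibroblast median was no smaller while its call was lost. The adjusted p ran from 0.00339 to 0.766 for collagen and from 0.00946 to 0.823 for fibroblast genes over the alternatives.

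**Figure D2:**
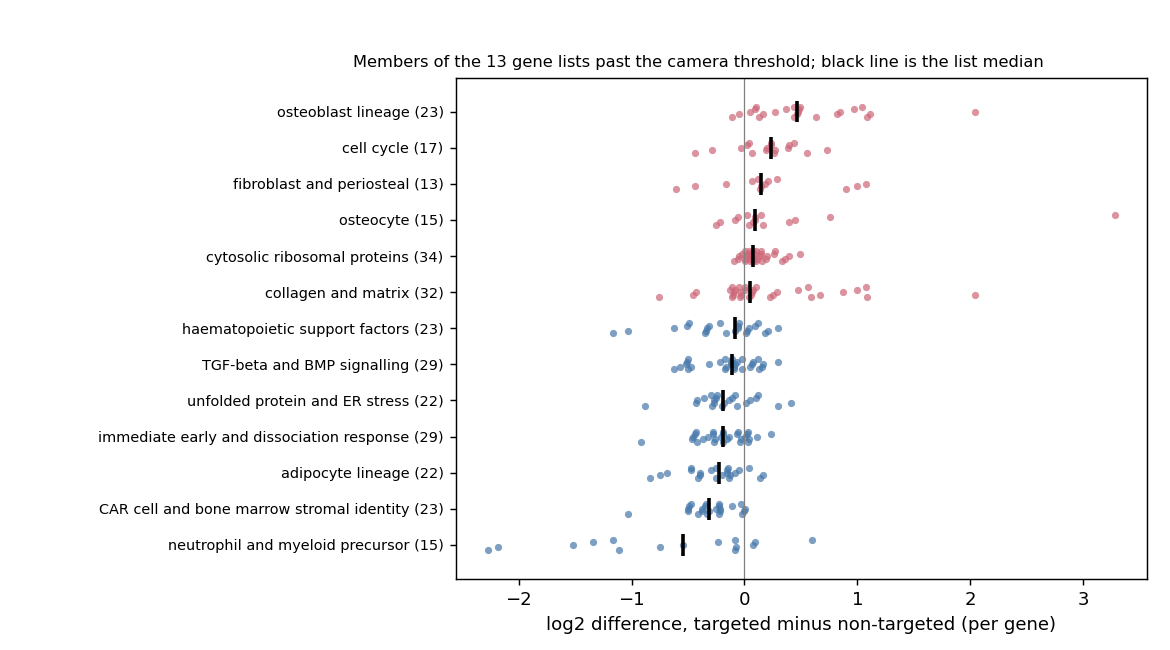
Log2 difference, targeted minus non-targeted, of each tested member (points) of the 13 gene lists past the camera threshold, with the list median as a black line and the number of members in brackets. Medians ran from -0.54 for neutrophil genes to 0.46 for osteoblast genes, and Dmp1 at 3.28 is the rightmost point of the osteocyte list.

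Neutrophil and myeloid precursor genes fell as a list, several members lying far lower on 1 targeted array. Of 15 tested members, 12 were lower and 3 higher, with a median of -0.54, a camera adjusted p of 0.0213 and adjusted p = 0.564 with an estimated correlation. S100a8 was at 6.97 in targeted replicate 1 and between 11.31 and 11.97 on the other 5 arrays, and Ngp was at 5.25 there and at 8.89 to 10.72 elsewhere. S100a9 was at 8.43 in that array against a mean of 11.80 over the others. Lcn2, a siderophore-binding protein gene, had the smallest p of the list and was low on 2 targeted arrays, at 5.86, 6.38 and 9.30 in targeted and 8.38 to 10.16 in non-targeted cells. Ltf, the lactoferrin gene, was at 5.87, 6.48 and 7.93 against 7.42 to 8.55, and Chil3 at 5.08, 5.59 and 6.65 against 6.29 to 6.90. Without targeted replicate 1 the list's median was -0.02 (adjusted p = 0.606) and without non-targeted replicate 3 it was -0.45 (adjusted p = 0.0684), within a range of 4.56e-06 to 0.608 over the alternatives. No member passed when adjusted over the list alone in the fit without a block. With the replicate number as a fixed block Lcn2 (limma, list-alone adjusted p = 0.0120), Ltf (0.0125) and Ngp (0.0368) did.

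**Figure D3:**
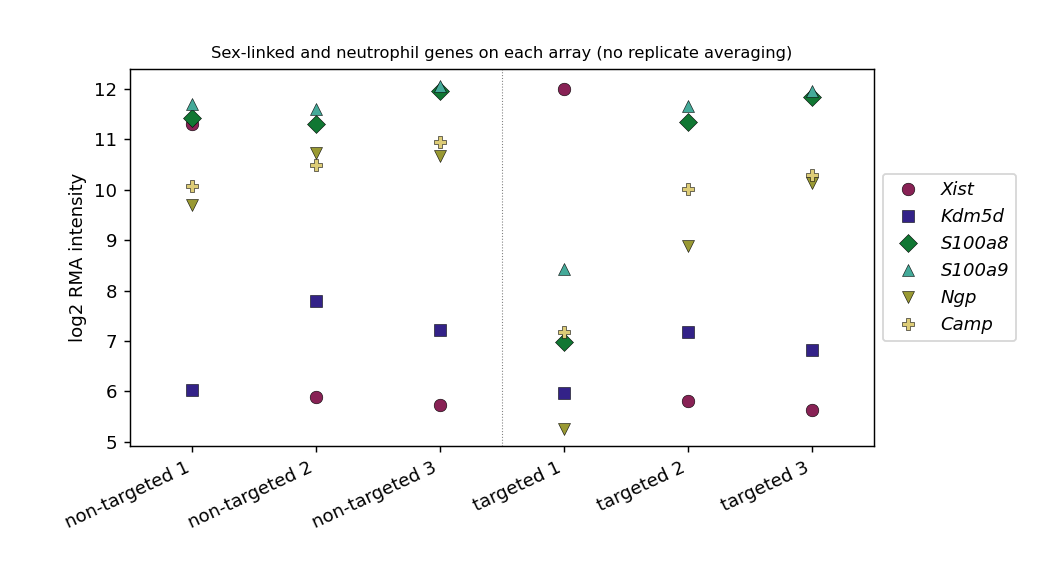
Log2 RMA intensity (vertical axis) of the sex-linked genes Xist and Kdm5d and of 4 neutrophil genes on each of the 6 arrays (horizontal axis), 1 point per array. S100a8 was at 6.97 in targeted replicate 1 and at 11.31 or above elsewhere, and Xist was at 11.31 and 12.004 on both replicate 1 arrays and at 5.64 to 5.88 on the rest.

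Lists of other marrow cell types did not pass. Their medians were 0.01 for macrophages (adjusted p = 0.869), 0.005 for B cells (0.917), -0.01 for progenitors and leukocytes in general (0.892), 0.003 for erythroid cells (0.698), 0.02 for megakaryocytes (0.396), 0.08 for osteoclasts (0.142), -0.18 for plasma cells (0.142), 0.04 for endothelial cells (0.441) and 0.09 for chondrocytes (0.347). The alpha globin genes, whose 2 probe sets name several genes and stayed out of the test, were lower in targeted cells on all arrays, at 8.38 against 9.39 and 8.34 against 9.36. The beta globin probe sets were at 10.62 against 10.96 and 10.63 against 11.02, with overlapping arrays. The median and the mean differed in sign for macrophages, B cells, megakaryocytes and chondrocytes. Of the tested B cell genes 4 were higher and 4 lower. Among them Vpreb1 was 2.91-fold lower, at 8.33, 6.22 and 6.98 in targeted and 9.19, 7.81 and 9.16 in non-targeted cells. It did not pass over the list alone without the replicate block (limma, adjusted p = 0.225). The pericyte and smooth muscle list (median 0.12, adjusted p = 0.235) held Abcc9, a channel subunit of pericytes, 1.68-fold higher and past the list-alone threshold (adjusted p = 0.0229), and Rgs5 at -0.83, which did not pass. The Schwann cell list (median 0.11, adjusted p = 0.0565) held Ncam1, a cell adhesion gene, 1.93-fold higher with a list-alone adjusted p of 0.0415. These list-alone calls were lost in 6 of 17 alternatives for Abcc9 and 9 of 17 for Ncam1. T and NK cell genes had 4 tested members and were not tested as a list.

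Of the pathway lists, ribosomal protein genes rose by a median of 0.08, 30 of 34 being higher (adjusted p = 0.0109, adjusted p = 0.615 with an estimated correlation). Cell cycle genes rose by 0.23, 14 of 17 being higher, with Cdk1 at 0.73 from a dim non-targeted level of 5.92 and Pcna at -0.43 (adjusted p = 0.0123, adjusted p = 0.485 with an estimated correlation). Immediate early and dissociation genes fell, 22 of 29 being lower with a median of -0.19, among them the heat shock gene Hspb1 at -0.92, Fosb at -0.44 and Dusp1 at -0.46 (adjusted p = 0.0106, adjusted p = 0.484 with an estimated correlation). Genes of the unfolded protein response fell, 16 of 22 being lower with a median of -0.19, among them Edem1 at -0.88 and Dnajb9 at -0.43 (adjusted p = 0.0382, adjusted p = 0.574 with an estimated correlation). Genes of TGF-beta and BMP signalling fell, 21 of 29 being lower with a median of -0.11, among them Bmp2 at -0.57, Chrdl1 at -0.63 and Acvr1 at -0.50 (adjusted p = 0.0402, adjusted p = 0.497 with an estimated correlation). No member of these 5 lists passed when adjusted over its list alone.

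These 5 pathway calls depended on single arrays. On replicates 2 and 3 alone the ribosomal median was -0.05. In leave-one-out fits the medians ran from 0.057 to 0.18 for ribosomal, 0.038 to 0.32 for cell cycle, -0.29 to -0.12 for immediate early, -0.32 to -0.074 for unfolded protein and -0.20 to -0.044 for TGF-beta genes. The cell cycle median was 0.038 without targeted replicate 1 and 0.12 without non-targeted replicate 2. Among members, Pcna ran from -0.66 to -0.13, Fosb from -0.62 to -0.29, Dusp1 from -0.60 to -0.25 and Dnajb9 from -0.54 to -0.26. Without targeted replicate 1 the ribosomal (adjusted p = 0.606), cell cycle (0.478) and immediate early (0.0893) calls ended. Without non-targeted replicate 2 the cell cycle (0.130), immediate early (0.0540), unfolded protein (0.377) and TGF-beta (0.307) calls ended. The ribosomal call also ended without non-targeted replicate 1 (0.0957), the immediate early call without non-targeted replicate 3 (0.0916), the unfolded protein call without non-targeted replicate 3 (0.162), targeted replicate 2 (0.170) or targeted replicate 3 (0.0727), and the TGF-beta call without targeted replicate 2 (0.177) or 3 (0.252). The adjusted p reached from 4.56e-06 to 0.868 for ribosomal, 0.000435 to 0.896 for cell cycle, 0.000124 to 0.507 for immediate early, 0.00173 to 0.574 for unfolded protein and 0.00826 to 0.553 for TGF-beta genes over the alternatives.

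The interferon response list did not pass (15 of 21 members lower, median -0.13, adjusted p = 0.0565). Cxcl10, an interferon-induced chemokine, was at 7.50 ± 0.28 in targeted and 8.84 ± 0.23 in non-targeted cells (SD, n = 3). It fell by 1.33 on the log2 scale, 2.52-fold, when adjusted over the list alone (limma, adjusted p = 0.00424), but not over all genes (adjusted p = 0.701). The list-alone call stayed in 17 of 17 alternatives, with an adjusted p of 0.000735 to 0.0282. These refits use the same arrays, and the call is not corrected for the number of lists, so chance is not excluded. Wnt signalling genes (adjusted p = 0.862) had a median of 0.01, while their mean of -0.05 and their test pointed the other way. Wif1 passed within the Wnt list alone (adjusted p = 0.0364), a call lost in 6 of 17 alternatives (adjusted p up to 0.167), among them fits without each non-targeted array and without targeted replicate 3. Lrp4, a receptor of sclerostin, was 2.41-fold higher without passing. Notch genes (median -0.04, adjusted p = 0.757), with Hey1 at 0.62, inflammatory cytokines (median -0.08, adjusted p = 0.142), hypoxia and glycolysis genes (median -0.08, adjusted p = 0.270) and oxidative phosphorylation genes (median 0.06, adjusted p = 0.142) did not pass.

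Outside the lists, the genes with the smallest p did not pass over all genes, each with an adjusted p of 0.701. Higher in targeted cells were Cpe, a carboxypeptidase that processes prohormones, at 9.15 ± 0.62 against 7.42 ± 0.35 (SD, n = 3), 3.31-fold, Slc36a2, an amino acid transporter, 2.14-fold, Pradc1, 2.38-fold, and Fam78b, 2.25-fold. Ccdc3, Hmgn5 and Ogfr were 2.01-fold, 1.78-fold and 1.76-fold higher. Larp1 was 2.54-fold higher by its brighter probe set, while its other probe set differed by 0.01 on the log2 scale. Lower in targeted cells were Ly6a2, at 5.13 ± 0.58 against 7.42 ± 0.59, Tmem184c (-1.48), the membrane-bound chemokine gene Cx3cl1 (-1.12), Pla1a (-1.06), the isocitrate dehydrogenase gene Idh1 (-0.99) and Ifitm1, an interferon-induced membrane protein gene (-0.92, and -1.17 by its other probe set). Aftph, Zfp9, Rpp38, Dclre1b and Pstk differed by -1.01 to -0.86. Ly6a2 and Aftph lay below the dim limit of 6.00 in targeted cells, so the size of their differences is uncertain.

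Sex-linked genes were read on each array as a check on the mice. Xist, the noncoding RNA of the inactive X chromosome, was at 11.31 in non-targeted replicate 1 and 12.004 in targeted replicate 1, and between 5.64 and 5.88 on the other 4 arrays. The Y-linked gene Kdm5d was at 6.02 and 5.96 on the replicate 1 arrays and at 6.82 to 7.79 on the others. The first principal component held 36.5% of the variance and had non-targeted replicate 2 and targeted replicate 1 at one end, at 25.2 and 28.5, with the other 4 arrays between -28.6 and 4.34.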

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

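The tests of targeted replicate 1 alone, admixed osteocytes, carried-over neutrophil RNA, a population difference in neutrophil genes, a shared mouse and the intensity spread were chosen only after the result was seen.

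A signal in data outside the comparison came from probe set 10342512, which the annotation pairs with no gene. It was at 7.03 to 7.29 in non-targeted and 3.23 to 3.57 in targeted cells (log2 difference -3.79, limma, SE 0.15), the latter below the dim limit of 6.00, so the size of the difference is uncertain, with an adjusted p of 0.00809 over 13767 probe sets kept out of the gene test. It belongs to 6617 probe sets whose identifiers lie below the lowest one listed, among which the real split of the arrays gave 1 call and the other splits gave 0 to 17.

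The osteoblast lineage list rose in targeted cells. Targeted replicate 1, which held the highest values, was not the whole cause, since without it the list's median log2 difference was still 0.34 and its camera call stayed at the preset correlation, a call that was lost over all arrays with an estimated one (adjusted p = 0.471). Osteocytes caught in the targeted sort were weighed as another source. The osteocyte list without Dmp1 had a median of 0.084, against 0.46 for osteoblast genes, with an SD of 0.27 between its 14 members. The SD was taken as the spread after the values were known, and the members reached up to 0.76 for Slc20a2. Only 7 members had a mean log2 intensity above 7, with a median of 0.037 and an SD of 0.36. An SD between genes is not the error of a median, and the other members lay nearer the dim limit. The osteocyte genes thus rose less than the osteoblast genes, but these values cannot decide on this source, which stays open. A difference between the sorted populations, which the design names, also stays open as a hypothesis.

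The neutrophil list fell most on targeted replicate 1. The 4 abundant members Ngp, S100a8, S100a9 and Camp lay lower on that array than the mean of the other 5, the smallest drop being -3.18 on the log2 scale. They were chosen by their level on those 5 arrays, so the drop does not tell neutrophil RNA carried over into 5 arrays from a difference between the sorted populations, and both stay open. Without that array the list's median was -0.024, but Lcn2 (6.38 against at least 8.38), Ltf, Chil3, Ngp and Camp on targeted replicate 2 still lay below the non-targeted range, while S100a8 and S100a9 did not. Lcn2 and Mmp9 also stand in other lists, and how much neutrophil RNA the sort for Cxcl12-gfp cells left was not measured here.

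Non-targeted replicate 2 and targeted replicate 1 deviated from their groups in the same direction (correlation across genes 0.32, genes not being independent replicates). They cannot be cells of the same mouse, as their Xist levels differed by 6.12 on the log2 scale. Both arrays had wider intensity distributions, with interquartile ranges of 2.60 and 2.55 against 2.27 to 2.43. After quantile normalization, which evens out the distributions, the correlation was still 0.253 (bootstrap range over genes 0.221 to 0.283). That range covers the sampling of genes only, for 1 pair of arrays picked for its high correlation. It therefore does not decide whether effects of the intensity spread were the whole cause. Amplification from small RNA amounts may differ between arrays and was not tested.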

How the results depend on the processing

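Fits without arrays chosen from the data, with the Xist class and with Dmp1 taken out of the lists were chosen after seeing the data, and the cause of a changed call was not tested unless stated. The osteoblast, CAR cell and adipocyte calls stayed in all 20 refits with the preset correlation, with medians of 0.24 to 0.54, -0.52 to -0.21 and -0.28 to -0.18. With an estimated correlation and with fry, 0 lists passed. The medians were unchanged, at 0.46 for osteoblast, -0.31 for CAR cell, -0.22 for adipocyte, 0.089 for osteocyte and -0.081 for haematopoietic support genes. Then 2 and 3 lists had an unadjusted p under 0.05, osteoblast and adipocyte genes among them. The estimated correlation was 0.225 for osteoblast, 0.370 for CAR cell and 0.354 for neutrophil and ribosomal genes, against the preset 0.01. Where members vary together that far, the p-values at the preset correlation are too small. For adipocyte genes the estimate was 0.0089.

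With the replicate block 1 gene passed (Dmp1, adjusted p = 0.0153, range 0.00886 to 1.00 over its alternatives), 576 had an unadjusted p under 0.05, and the 13 list calls were the same. Adjusted over each list alone, 7 calls became 15 with the block: gained were Alpl (adjusted p = 0.0160), Postn (0.0148) and Col1a1 (0.0424) among osteoblast genes, Postn among matrix genes (0.0206), Lcn2 (0.0120), Ltf (0.0125) and Ngp (0.0368) among neutrophil genes, Lcn2 among inflammatory genes (0.0136), Il7 in 2 lists (0.0296 each) and Vpreb1 (0.00545), while Abcc9 (0.1005), Ncam1 (0.0813) and Wif1 among Wnt genes (0.0791) no longer passed. Same-numbered arrays deviated together at -0.26, -0.12 and 0.07, and 1 of 6 arrays correlated best with its own number. Xist was high on the replicate 1 arrays only. If both populations came from the same 3 mice, as the design text reads, these 2 arrays share a mouse. They nevertheless gave the value of -0.26, so this correlation cannot tell whether the numbers pair the arrays, and pairing stays open. Array weights also gave 1 gene, Dmp1 (2060 with an unadjusted p under 0.05). Non-targeted replicate 3 had a weight of 6.05 there and the other arrays 0.36 to 1.26. That fit thus rested mostly on 1 array for the non-targeted group. The Xist class gave 1 gene, again Dmp1. All other fits gave 0 genes. Among these, the fit with the replicate number as a random block had Dmp1 at an adjusted p of 0.9999 over all genes. Its list-alone calls of Alpl and Il7 among the single genes (limma, adjusted p = 0.105 each), Abcc9 (0.0539), Ncam1 (0.0627) and Wif1 among Wnt genes (0.0689) were lost. Those of Dmp1, Mmp13, Cxcl10 and, among osteoblast genes, Wif1 stayed.

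The lists past the threshold numbered 8 with cyclic loess, 5 with array weights, 8 on replicates 2 and 3 alone, 3 without both outer arrays of the first component, and 6 to 12 when each array was left out. The osteocyte call was lost with no filter on dim genes (0.084), quantile (0.092) and loess scaling (0.092), array weights (0.14), replicates 2 and 3 alone (0.22), without both outer arrays (0.10) and without Dmp1 (0.084), and medians ran from 0.022 to 0.14 in leave-one-out fits. The haematopoietic support call was lost with loess (-0.071), array weights (-0.20) and without both outer arrays (-0.13), and medians ran from -0.26 to -0.11 in leave-one-out fits. On replicates 2 and 3 alone the ribosomal median turned to -0.049, Rpl30 to -0.011, Rplp0 to -0.13 and Rps2 to -0.087. The interferon list, past no threshold in the report, passed in 6 fits. Pdgfrb ran from -0.33 to 0.11 in leave-one-out fits. Of 1653 values of 83 named genes over 20 settings, 5 turned direction. As none of these genes passed over all genes in the main fit, a threshold kept there says little. Rescaling moved the median of all genes to at most 0.04. Genes below the dim limit of 6.00 were not tested, so low signal limits what could be called there.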

Other observations

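The splits of the arrays were counted after seeing the results, except those of the osteocyte and haematopoietic support lists.

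The 6 arrays can be split 3 against 3 in 10 ways, so no share of splits under 0.1 can be reached. The real split gave 0 genes past the threshold, as did the other splits, so 10 of 10 gave as many. It gave 13 lists, against 1 to 10 for the other splits, so 1 of 10 gave as many. Every other split thus also gave list calls. For the osteoblast list -log10 of the camera p was 12.1 against 6.01 for the highest other split, for the CAR cell list 6.503 against 5.97, for the adipocyte list 3.80 against 2.10 and for the osteocyte list 2.09 against 2.02, and in each case 1 split reached the real value. For haematopoietic support genes it was 1.96 against 3.07, and 2 splits reached it. Another split set non-targeted replicate 1 with targeted replicates 2 and 3 against the rest. It gave 2617 genes with an unadjusted p under 0.05, against 634 for the real split, which points to a structure of the arrays other than the groups. The value of 5.97 for the CAR cell list came from this split, so that list followed this structure nearly as closely as the groups.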
